A study of Mus musculus with 36 samples.

How the data were processed

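RNA of the dorsal vagal complex was sequenced in 36 libraries. This brainstem region holds the solitary tract nucleus and the dorsal motor nucleus of the vagus nerve, which receive and send the signals of the gut and take part in the control of food intake. Per the labels, the mice were of 3 inbred strains and both sexes. C57BL/6J is a common laboratory strain, CAST/EiJ a wild-derived strain, and NZO/HlLtJ a strain prone to obesity and diabetes. From 6 weeks of age until tissue collection at 15 weeks the mice ate a control diet with 10% fat, or a diet high in fat and sugar with 44% fat, called HFHS here, both with added fiber. Each of the 12 groups of strain, diet and sex held 3 libraries, numbered here in the order of the labels. Per the labels' protocols, libraries of polyA RNA were made with the KAPA mRNA HyperPrep kit from 100 ng of RNA with ERCC spike-in RNA added, and were sequenced with paired-end reads of 100 bp to a target of 30 M read pairs (M, 1e6). The labels give no collection day and no sequencing batch.

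The deposited table of expected counts, which are estimated counts that need not be whole, holds 24344 Ensembl genes. Between 18.8% and 22.7% of the values of a library lay further than 1e-06 from a whole number, and the totals ran from 22.03 to 49.61 M. Every gene in the table was above 0 in at least 19 of the 36 libraries, and the table held 0 spike-in sequences. The genome build GRCm38 and the program DESeq2 are named per the submitters' processing notes, without a version or a role for the program. The aligner, the counting program and the annotation release are not given in the sources used here, nor whether the counting used the strand of the reads. A deposited table of log2 values holds a variance-stabilising transformation (VST) of the same genes and libraries. DESeq2's transformation of the rounded counts differed from it by at most 0.163 log2 units. Symbols were taken from the deposited annotation, in which 39 symbols occur more than once. Coordinates and gene types were taken from gencode vM21 on GRCm38, which held 24191 of the identifiers.

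The expected counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1 and R 4.3.3). Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20108 genes. Library sizes were scaled by the trimmed mean of M values (TMM), with factors from 0.959 to 1.04. A mean was fitted for each of the 12 groups over all libraries together, with 24 residual degrees of freedom and a common biological coefficient of variation of 0.163. Contrasts of these means gave the effect of diet in each strain, the differences between strains, the effect of sex in each strain, and the interactions. An adjusted p is a Benjamini-Hochberg value over the genes of a contrast from this test unless another tool is named, and a gene is called when it is under 0.05. Effects are log2 fold changes with their standard error (SE), and levels are counts per 1e6 counts (CPM) with their standard deviation (SD) over libraries. Differences are given as HFHS minus control, male minus female, or as the strains are named.

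Gene lists, contrasts, tests, alternatives and the rule for named genes were fixed before the data were examined, with exceptions. The 3 alternatives named as added below, the choice of the lists described in each contrast, and the numbers of splits were settled after results had been seen. Some lists were dropped from that choice after values of their members had been seen to change sign under an alternative. The plan named only lists of 3 or more tested genes for the list tests, but the list of Nnt and Gabra2 was tested. The 45 gene lists cover pathways, cell types of the region and of tissue around it, and checks of strain and sex. Each was tested in the 15 contrasts of 1 degree of freedom by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with a correlation estimated from the data, and fry, were alternatives, and a count of members "adjusted over the list alone" uses only the members of that list. The preset test assumes nearly independent genes, so the p with an estimated correlation stands beside it. Of the 675 list tests, 148 passed with the preset correlation, 9 with an estimated correlation and 51 with fry. The mean log2 CPM of a list's genes in a library is called its score. Scores were compared between diets within each strain by an exact two-sided permutation test over the 400 ways to redraw the diets within sexes. This test cannot give a p under 0.005. Benjamini-Hochberg adjustment was over all scores of the 3 strains, and with that floor no score can pass it by its own shift alone.

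Named genes were, for each contrast, the 10 largest rises and the 10 largest falls among called protein-coding genes with an average log2 CPM of at least 1, a symbol other than a gene model name, and the same sign in both sexes (for sex contrasts, on both diets; for interactions, no such condition). A few genes that meet this rule are left out of the text. Tests of 2 degrees of freedom named the smallest adjusted p values. Added to these were up to 4 members with the smallest adjusted p of each list described, and all members of the strain and sex checks. To find genes whose reads can be split with a near-identical copy, the share of each gene's 50-base sequences that also occur in another annotated gene was counted from the transcripts of 55450 genes. A fold against a group without any count is given as a lower bound against 3 counts over the group, and such bounds cover counting error only.

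Alternatives were size factors by the median of ratios (RLE), DESeq2 1.42.0, no filter on low counts, limma on the deposited log2 values, 2 surrogate variables (sva 3.50.0), a fit of only the strain's libraries, an additive model, and leaving out each library in turn. After the data had been seen, 3 more were added: leaving out 3 libraries almost without reads of Hox genes, a score of 19 Hox genes as a covariate, and the Hox, cerebellar and choroid plexus scores as covariates. Leaving out these libraries keeps male control 2 as the only CAST/EiJ male control, so the CAST/EiJ results of that fit lean on that library. For each count of called genes, the same fit was repeated on 60 splits of the libraries (30 for the strain contrasts), the real split included. In counts simulated from the means and spread of the libraries with 200 genes changed per fold, edgeR's test of diet in NZO/HlLtJ recovered 148 genes at a fold of 1.5, 181 at a fold of 2 and 194 at a fold of 4 among 19684 genes. For the interaction of diet and sex in CAST/EiJ these numbers were 72, 134 and 181. False calls were 2.06% and 2.52% of the calls in these contrasts, and 7.84% in the contrast of CAST/EiJ and C57BL/6J. Each gene was drawn independently around 1 mean, so the simulated libraries share no differences in tissue content. The rates hold for such counts and need not hold for the real libraries.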

Results

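Gene expression in the dorsal vagal complex was measured in 36 libraries, 3 for each combination of strain (C57BL/6J, CAST/EiJ, NZO/HlLtJ), diet (control with 10% fat, HFHS with 44% fat) and sex. The series asks how genotype and diet together set susceptibility to type 2 diabetes in these mouse models. Total counts per library (M, 1e6 counts) ran from 22.03 M in CAST/EiJ male HFHS 1 to 49.61 M in NZO/HlLtJ male control 3. Group means of the total lay between 32.1 ± 5.36 M (SD, n = 3) in C57BL/6J female HFHS and 44.0 ± 5.72 M (SD, n = 3) in NZO/HlLtJ female HFHS. The first principal component of the libraries held 39.4% of the variance, the next 12.4%.

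Libraries differed in their reads of Hox genes, and the labels give no level of dissection. Hox genes, which are expressed in the hindbrain behind its anterior border and in the spinal cord, summed to 1.15 CPM in CAST/EiJ male control 1, 1.93 CPM in CAST/EiJ male control 3 and 2.74 CPM in NZO/HlLtJ male control 3. In the other 33 libraries the sum lay between 20.5 and 360.7 CPM. The mean score of 19 Hox genes in CAST/EiJ was -0.24 ± 2.83 (SD, n = 6) on the control diet and 3.29 on HFHS, a difference of 3.53 log2 units (exact two-sided permutation test, p = 0.01, adjusted p = 0.138). In NZO/HlLtJ the score was 1.77 higher on HFHS (exact permutation p = 0.115) and in C57BL/6J 1.13 higher (exact permutation p = 0.28). Gabra6, a marker of cerebellar granule cells, reached 223.1 CPM in CAST/EiJ male control 1 and 315.4 CPM in CAST/EiJ male control 3, while NZO/HlLtJ male control 1 had 2.15 CPM.

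**Figure D1:**
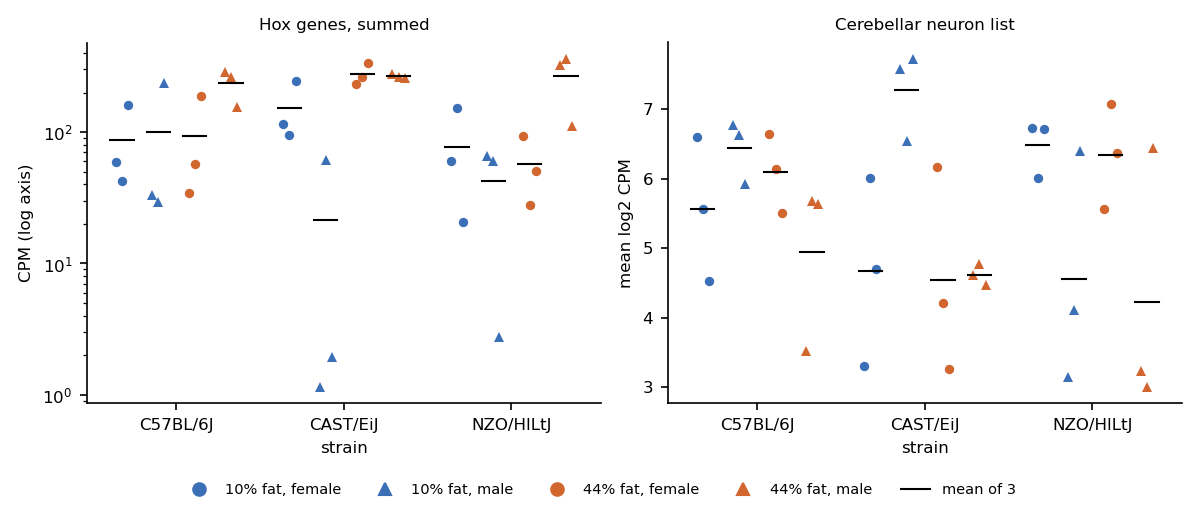
Summed CPM of Hox genes on a log axis (left) and the mean log2 CPM of the cerebellar neuron list (right) in each of the 36 libraries, by strain, with the diet as colour, the sex as symbol and a line at the mean of 3 libraries. CAST/EiJ male control 1 and 3 and NZO/HlLtJ male control 3 lie at 1.15, 1.93 and 2.74 CPM of Hox reads, and the other 33 libraries at 20.5 CPM or above.

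Diet was compared within each strain to ask which genes of this region responded to the high-fat, high-sugar food. In NZO/HlLtJ, 3 genes of the heat shock list were called lower on HFHS, and camera called the list with the preset correlation but not with an estimated one. Hspa1b (ENSMUSG00000090877; chromosome 17, 34956436 to 34959238) and Hspa1a (ENSMUSG00000091971; chromosome 17, 34969190 to 34972156), which encode the stress-inducible HSP70 chaperone, fell from 56.8 ± 40.8 to 3.94 ± 0.924 CPM and from 55.7 ± 38.9 to 9.26 ± 0.764 CPM (SD, n = 6 per diet). Their log2 changes were -3.70 (SE 0.58) and -2.45 (SE 0.38), both with adjusted p = 0.0138 in edgeR's test. Each of the 6 HFHS libraries lay below each of the 6 control libraries for both genes. The genes share about 60.8% and 61.7% of their 50-base sequences with each other, so the split of reads between them is uncertain. Hsph1 (ENSMUSG00000029657), an HSP110 co-chaperone, fell by 0.59 (SE 0.11, adjusted p = 0.0365 in edgeR's test), and Ahsa2, related to an activator of the HSP90 ATPase, by a log2 change of -0.56.

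All 11 tested genes of the heat shock list had lower values on HFHS in NZO/HlLtJ, 3 of them called over all genes and 11 lower when adjusted over the list alone, with a median log2 change of -0.38. Camera called the list lower (adjusted p = 9e-20 with the preset correlation; adjusted p = 0.11 with an estimated correlation). The heat shock score lay between 6.54 and 6.77 in the HFHS libraries and between 7.19 and 7.95 in the controls. The difference was -0.86 (exact two-sided permutation p = 0.005, the smallest the test can give, adjusted p = 0.138). With that smallest p, no score can pass the adjustment by its own shift alone. Of 20 genes of the endoplasmic reticulum and integrated stress response, 0 were called by edgeR and 14 were lower when adjusted over the list alone, with a median of -0.41 (camera adjusted p = 2e-15; adjusted p = 0.122 with an estimated correlation). Among its members, the luminal chaperone Hsp90b1 had a log2 value of -0.44 (SE 0.09, adjusted p = 0.0549 in edgeR's test) and the disulfide isomerase Pdia4 of -0.61 (SE 0.13, adjusted p = 0.0696 in edgeR's test). Immediate early genes, which mark recent neuronal activity, had a median of -0.56 (camera adjusted p = 2.5e-05; adjusted p = 0.819 with an estimated correlation), with Fosl2 at -1.02 and Npas4 at -0.74. Red blood cell genes had a median of -1.15 (camera adjusted p = 1e-04; adjusted p = 0.485 with an estimated correlation), with Hbb-bs at 294.5 CPM on HFHS and 646.8 CPM on control.

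Of the 10 genes called for diet in NZO/HlLtJ, 2 were higher and 8 lower. Fam46a, a poly(A) polymerase, had a log2 change of -1.15 (SE 0.22), the nucleosome-binding Hmgn1 of -0.35 (SE 0.07), the kinase Taok3 of -0.29 (SE 0.06), and Whamm, a promoter of actin branching, rose by 0.31 (SE 0.06), each with adjusted p = 0.0365 in edgeR's test. NZO/HlLtJ male control 1, a library with reads of pituitary hormones, was high for Fam46a (66.2 CPM) and Hmgn1 (65.3 CPM). Without it their changes were -0.76 and -0.27 (adjusted p = 0.0738 and 0.0983 in edgeR's test). That library also had the highest score of the stress response list among the NZO/HlLtJ controls, 5.75 against 5.29 to 5.46. DESeq2 called 105 genes, the additive model 23, the fit with the Hox score as a covariate 5, and the fit with 3 tissue scores 0. Without the 3 libraries almost lacking Hox reads, 169 were called. Leaving out any 1 of the 6 NZO/HlLtJ HFHS libraries left 0 calls. Leaving out female control 1, female control 2, male control 1, CAST/EiJ female control 3 or C57BL/6J male HFHS 3 left 2. Male control 2 gave 91 and male control 3 gave 94. The count was 3 without C57BL/6J male HFHS 2, 4 without C57BL/6J female control 2, 5 without CAST/EiJ female HFHS 2, 6 without CAST/EiJ female HFHS 1. It was 19 and 36 without CAST/EiJ male control 3 and 1, 21 without C57BL/6J female HFHS 3, and 22 without C57BL/6J male control 2 or female HFHS 2.

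**Figure D2:**
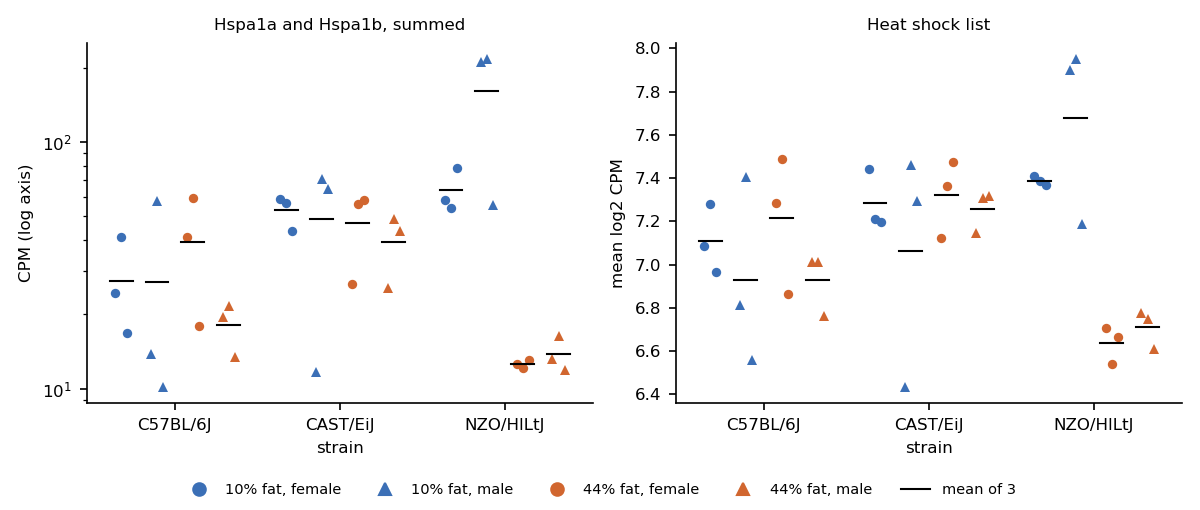
Summed CPM of Hspa1a and Hspa1b on a log axis (left) and the mean log2 CPM of the heat shock list (right) in each of the 36 libraries, by strain, with the diet as colour, the sex as symbol and a line at the mean of 3 libraries. The NZO/HlLtJ HFHS libraries have list scores between 6.54 and 6.77, below the 7.19 to 7.95 of the NZO/HlLtJ controls.

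In CAST/EiJ, 54 genes were called for diet, 23 higher and 31 lower on HFHS. Gfap (ENSMUSG00000020932; chromosome 11, 102887336 to 102900912), the filament protein of astrocytes, rose from 334.6 ± 148.8 to 677.2 ± 44.0 CPM (SD, n = 6 per diet; log2 1.09, SE 0.22, adjusted p = 0.0335 in edgeR's test). Prrxl1 (ENSMUSG00000041730), a transcription factor of sensory neurons of the dorsal hindbrain and spinal cord, rose by 1.46 (SE 0.33, adjusted p = 0.047 in edgeR's test). Other rises were those of the Wnt antagonist Frzb (1.22), Brca1 (1.00), the phosphodiesterase Pde11a (0.90), the complement gene C4b (0.80, with 34.3% of its 50-base sequences shared with C4a), the receptor gene Trhr (0.66), Prr5l (0.62), Skap2 (0.56) and Tekt5 (0.44). Genes of red blood cells fell: Alas2 (ENSMUSG00000025270; chromosome X, 150547375 to 150570638), which starts haem synthesis in red cells, went from 25.9 ± 13.9 to 3.41 ± 0.659 CPM (SD, n = 6; log2 -2.92, SE 0.52, adjusted p = 0.0189 in edgeR's test), and the globin genes Hbb-bt, Hbb-bs and Hba-a2, which share between 52.6% and 96.1% of their sequences with other globin genes, had changes of -2.86, -2.68 and -2.67. Outside the blood, the peptide gene Spx had a change of -1.63, Col9a1 of -1.44, Tspan9 of -0.81, Tuba8 of -0.71, Slc16a6 of -0.69 and Tmem132a of -0.68.

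By list, 4 of 6 red blood cell genes were lower in CAST/EiJ on HFHS (5 when adjusted over the list alone; camera adjusted p = 4.5e-08, adjusted p = 0.246 with an estimated correlation). Reactive astrocyte genes had 1 of 14 members higher, and 5 when adjusted over the list alone (median 0.37; camera adjusted p = 2.4e-04, adjusted p = 0.308 with an estimated correlation), and Serpina3n had a log2 value of 0.68 without passing. Myelin genes had 0 of 14 called by edgeR and 12 higher when adjusted over the list alone (median 0.31; camera adjusted p = 3.3e-08, adjusted p = 0.521 with an estimated correlation), with Ermn at 0.49 and Cldn11 at 0.41. Cerebellar neuron genes had a median of -1.47 (0 of 12 called by edgeR, 1 lower when adjusted over the list alone; camera adjusted p = 4.7e-07, adjusted p = 0.521 with an estimated correlation). Microglial genes had a median of 0.21 (camera adjusted p = 1.5e-04) and feeding-related peptides of 0.23 (camera adjusted p = 0.00143), and with an estimated correlation each had an adjusted p = 0.521. Within the peptides, Tac2 had 4.34 CPM on HFHS and 1.14 CPM on control, and Trh 10.7 and 3.24 CPM, and neither was called.

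These CAST/EiJ values moved with the Hox reads of the libraries, those of the red blood cell genes less than the others. Leaving out the 3 libraries almost lacking Hox reads keeps male control 2 as the only CAST/EiJ male control. The 4 called red blood cell genes then kept a median of 0.992 of their diet effect. The other 50 called genes kept 0.75. With the Hox score as a covariate these medians were 0.744 and 0.519. With the Hox score as a covariate edgeR called 0 genes, the medians of the myelin, reactive astrocyte and microglial lists were 0.02, 0.06 and 0.02, that of the cerebellar list was 0.29, and that of the red blood cell list was -1.96. DESeq2 called 753 genes, limma on the deposited log2 values 277, and the fit of only CAST/EiJ libraries 140. Fewer came from the additive model (5), 2 surrogate variables (0) and the fit without the 3 libraries almost lacking Hox reads (4). Leaving out 1 CAST/EiJ library left 0 calls without female HFHS 2 or female control 2, 1 without male HFHS 1 or female HFHS 3, 2 without male control 3. It was 9 without male HFHS 3, 10 without male control 1 or male HFHS 2, 95 without female control 3, 219 without female HFHS 1 and 1928 without male control 2. Without male control 2, the CAST/EiJ male controls left are male control 1 and 3, with 1.15 and 1.93 CPM of Hox reads. Leaving out NZO/HlLtJ male control 1, 2 or 3 gave 84, 204 and 413, NZO/HlLtJ male HFHS 3 gave 115 and C57BL/6J male control 3 gave 90.

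In C57BL/6J no gene was called for diet: edgeR called 0 of 20108 genes, with 525 at an unadjusted p under 0.05, and DESeq2 called 0. Those 525 are fewer than the share of 0.05 that chance alone would give, so they are no sign of a response. The count of 0 does not show that diet had no effect. Among genes that respond to glucocorticoids, Ddit4 had 30.9 CPM on HFHS and 44.3 CPM on control, and Sgk1 135.3 and 216.7 CPM. The list had a median of -0.18 (camera adjusted p = 2.2e-04, adjusted p = 0.834 with an estimated correlation). Feeding-related peptides had a median of 0.21 (camera adjusted p = 0.00161, adjusted p = 0.834 with an estimated correlation), led by Gcg, the gene of glucagon-like peptides, with 1.35 CPM on HFHS and 0.148 CPM on control. Gcg went with the Hox score of the C57BL/6J libraries. It was at most 0.0259 CPM in the 6 with a score of 0.30 or below and at least 0.319 CPM in the 6 with 2.20 or above. With the Hox score as a covariate, camera with the preset correlation called 0 of the 45 lists for diet in C57BL/6J instead of 11. The peptides then had a median of 0.13 (adjusted p = 0.0764). The count was 1 without C57BL/6J female control 3 and 3 without C57BL/6J male control 2.

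The interaction of strain and diet asks whether the response to the food depended on genotype. EdgeR called 0 genes, with 1726 at an unadjusted p under 0.05, and DESeq2 called 47. Heat shock genes differed in their diet effects as a list: 10 of 11 were lower in NZO/HlLtJ than in C57BL/6J and 11 of 11 lower in NZO/HlLtJ than in CAST/EiJ when adjusted over the list alone, with medians of -0.46 and -0.57. Camera called both (adjusted p = 1.8e-16 and 2.6e-19), and with an estimated correlation the adjusted p = 0.201 and 0.121. Without the 3 libraries almost lacking Hox reads these were 0.0175 and 0.0193, and for the heat shock list in NZO/HlLtJ the adjusted p = 0.00699 with an estimated correlation. That fit leaves out NZO/HlLtJ male control 3, which had the lowest heat shock score of the NZO/HlLtJ controls (7.19). It also keeps male control 2 as the only CAST/EiJ male control. For Hspa1b the diet effect in NZO/HlLtJ differed from that in C57BL/6J by -3.53 (SE 0.78, adjusted p = 0.35 in edgeR's test) and from that in CAST/EiJ by -3.35 (SE 0.76, adjusted p = 0.111 in edgeR's test). In single pairs of strains edgeR called 0 genes for NZO/HlLtJ against C57BL/6J (1307 at an unadjusted p under 0.05, 10 by DESeq2), 0 for CAST/EiJ against C57BL/6J (1309; 7 by DESeq2) and 0 for NZO/HlLtJ against CAST/EiJ (2214; 60 by DESeq2). The interaction count was 42 without CAST/EiJ male control 2, 19 without NZO/HlLtJ male control 3, 8 without C57BL/6J male control 2, and 1 without CAST/EiJ male control 3 or C57BL/6J female control 3. Without CAST/EiJ male control 2, the CAST/EiJ male controls left almost lack Hox reads.

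Strain differences were far larger than diet differences. The processing notes name 1 genome build, GRCm38, for the libraries of all strains. Single genes in the 3 strain contrasts may therefore carry a difference in mapping, which was not tested. Between NZO/HlLtJ and C57BL/6J, 4792 genes were called, 2345 higher and 2447 lower in NZO/HlLtJ. Npsr1 (ENSMUSG00000043659; chromosome 9, 24097996 to 24316398), the receptor of neuropeptide S, was at 19.94 ± 3.67 CPM in NZO/HlLtJ and 0.794 ± 0.332 CPM in C57BL/6J (SD, n = 12; log2 4.68, SE 0.15, adjusted p = 3.3e-21 in edgeR's test). The phospholipase gene Pla2g4e was higher by 3.17 (SE 0.09). Lower in NZO/HlLtJ were Fcrls (ENSMUSG00000015852), a gene of homeostatic microglia, with 0.793 ± 0.240 against 8.68 ± 1.21 CPM (log2 -3.44, SE 0.13, adjusted p = 1.1e-19 in edgeR's test). So were the cohesin gene Rec8 (-4.04), Bfsp2 (-3.35), Fggy (-3.24), Eps8l1 (-3.11), Pttg1 (-3.07), Myoc (-2.97), Tceanc2 (-2.89) and Mid1 (-2.56). Complement genes of microglia were lower too: C1qa at -0.57, C1qb at -0.65 and C1qc at -0.58. Of 15 microglial genes, 5 were lower and 2 higher (camera adjusted p = 0.0827, adjusted p = 0.96 with an estimated correlation).

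Receptors for gut and feeding signals differed in a few members. Gipr (ENSMUSG00000030406; chromosome 7, 19156061 to 19166127), the receptor of the incretin GIP, was at 0.996 ± 0.245 CPM in NZO/HlLtJ and 3.06 ± 0.559 CPM in C57BL/6J (SD, n = 12; log2 -1.61, SE 0.13, adjusted p = 1.3e-11 in edgeR's test). Htr3a (ENSMUSG00000032269), a subunit of the serotonin-gated channel of vagal pathways, was at 0.898 and 2.19 CPM (log2 -1.36, SE 0.28, adjusted p = 5.2e-04 in edgeR's test), and Cckbr, a receptor of cholecystokinin and gastrin, was higher by 0.30 (SE 0.11). These were the 3 called members of 25 receptors, while 4792 of all 20108 tested genes were called. The list's median was 0.04 and its mean -0.09, and camera did not call it (adjusted p = 0.916). Of 21 feeding-related peptides edgeR called 0 (camera adjusted p = 0.916). Among candidate genes from crosses with NZO mice, Apoa2 was lower in NZO/HlLtJ (0.00686 against 0.25 CPM, close to no counts), Pctp was higher by 0.29, and Abcg1, Tbc1d1, Lepr and Zfp69 were not called, with values of 0.07, -0.06, 0.04 and 0.14.

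**Figure D3:**
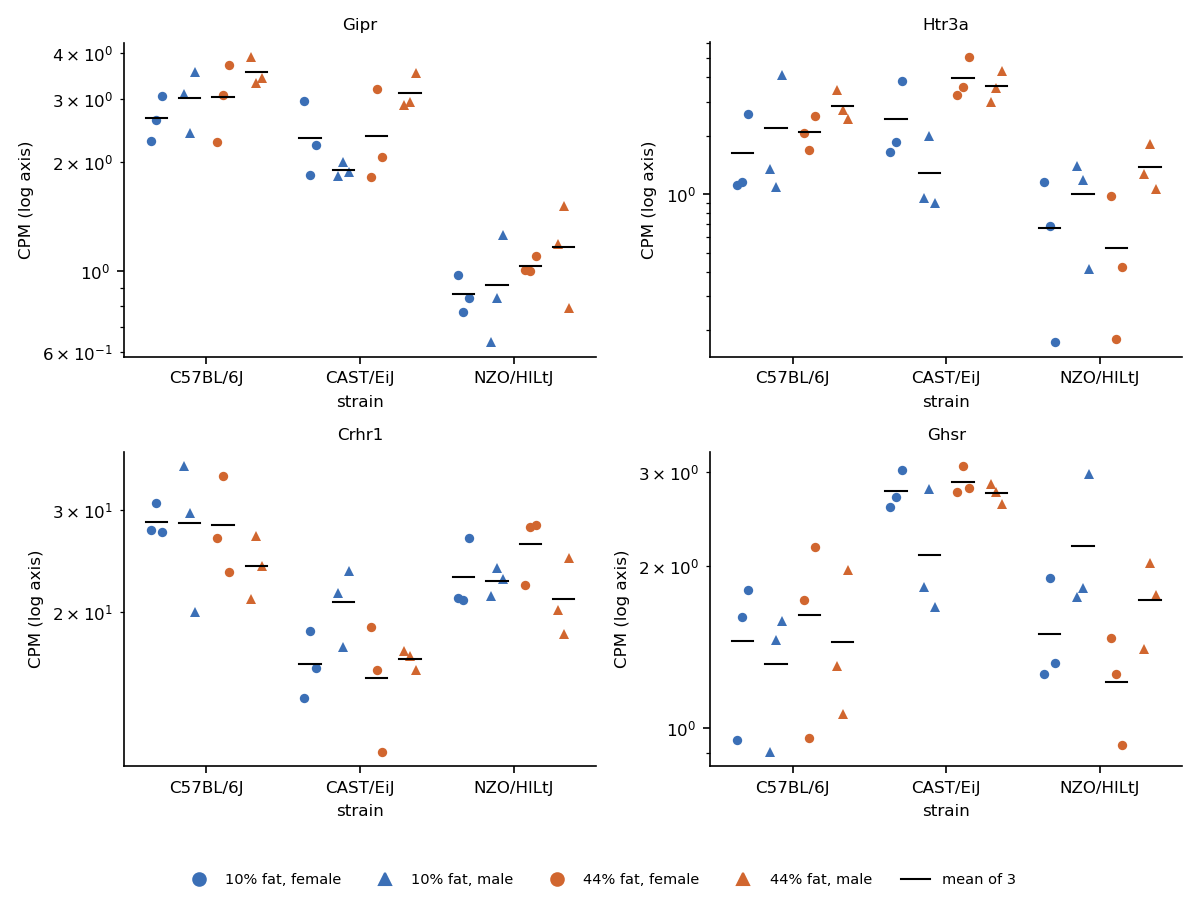
CPM on a log axis of the receptor genes Gipr, Htr3a, Crhr1 and Ghsr in each of the 36 libraries, by strain, with the diet as colour, the sex as symbol and a line at the mean of 3 libraries. Gipr averages 0.996 CPM in NZO/HlLtJ and 3.06 CPM in C57BL/6J, and Ghsr 2.62 CPM in CAST/EiJ and 1.46 CPM in C57BL/6J.

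CAST/EiJ and C57BL/6J differed in 10492 genes, 4921 higher and 5571 lower in CAST/EiJ. Genes of the innate immune response to viruses were lower in CAST/EiJ: of 20 interferon-stimulated genes, 17 were lower and 1 higher, with a median of -1.13 (camera adjusted p = 5.1e-06, adjusted p = 0.225 with an estimated correlation). Oasl2 (ENSMUSG00000029561; chromosome 5, 114896936 to 114912234) was at 1.13 ± 0.328 against 7.78 ± 1.35 CPM (SD, n = 12; log2 -2.79, SE 0.13, adjusted p = 1.1e-17 in edgeR's test). The transcription factor gene Irf7 had a difference of -2.24 (SE 0.12), Trim30a of -1.53 (SE 0.10) and Ifit3, which shares 54.1% of its 50-base sequences with Ifit3b, of -2.30 (SE 0.13). Of 16 antigen presentation genes, 12 were lower and 2 higher (median -0.67; camera adjusted p = 0.00257, adjusted p = 0.857 with an estimated correlation), with the class I genes H2-D1 at -2.97 (SE 0.07) and H2-K1 at -2.44 (SE 0.12). H2-D1 shares 16.1% of its 50-base sequences with H2-Q1, and these genes vary in sequence between strains, so their levels are uncertain.

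Markers of several cell types were lower in CAST/EiJ than in C57BL/6J. Myelin genes had 13 of 14 members lower (median -0.60; camera adjusted p = 1.1e-05, adjusted p = 0.749 with an estimated correlation), with Mobp at 1238 ± 213.3 against 2529 ± 237.4 CPM (SD, n = 12). Pericyte and smooth muscle genes had 7 of 10 lower (median -0.51; camera adjusted p = 0.00257, adjusted p = 0.707 with an estimated correlation), with Rgs5 at -1.39 (SE 0.05) and Vtn at -1.09 (SE 0.08). Among microglial genes 8 of 15 were lower and 1 higher (median -0.37; camera adjusted p = 0.0176, adjusted p = 0.812 with an estimated correlation), with the complement gene C1qc at -0.98, and among endothelial genes 10 of 14 were lower and 1 higher (median -0.31; camera adjusted p = 0.0221, adjusted p = 0.749 with an estimated correlation), with the tight junction gene Ocln at -0.41. Of 25 feeding-related receptors 7 were higher and 3 lower, while of all 20108 tested genes 4921 were higher and 5571 lower. The ghrelin receptor gene Ghsr (ENSMUSG00000051136) was at 0.85 (SE 0.15, adjusted p = 1.5e-05 in edgeR's test), Npy5r at 0.52 and Ramp2 at 0.35. The receptor gene Crhr1 (ENSMUSG00000018634) was at -0.67 (SE 0.09). Of 21 peptides 6 were higher, among them Tac1 (0.57), Nmb (0.52), Pdyn (0.51) and Nucb2 (0.32), and camera called neither list (adjusted p = 0.482 and 0.184).

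The largest single-gene differences of CAST/EiJ included the matrix gene Thbs4 (ENSMUSG00000021702; chromosome 13, 92751590 to 92794818) at 38.9 ± 7.90 against 0.883 ± 0.260 CPM (SD, n = 12; log2 5.44, SE 0.14, adjusted p = 4.5e-23 in edgeR's test). So were the taste receptor gene Tas1r1 at 64.5 against 2.32 CPM, the galectin-related gene Grifin at 9.61 against 0.106 CPM and the channel subunit gene Kcnmb3 at 6.31 against 0.0329 CPM. Fam213b (ENSMUSG00000029059, chromosome 4, 154895504 to 154899135), which encodes a prostamide synthase, was at 0.0214 ± 0.0522 against 42.7 ± 3.23 CPM (SD, n = 12). Its fitted log2 difference of -11.74 rests on almost no counts in CAST/EiJ, so the size is uncertain. Other genes far lower in CAST/EiJ were Myoc (-6.89), Cideb (-6.15), Serpinb1a (-5.70), Rec8 (-5.63) and Lpo (-5.15), which share under 5% of their 50-base sequences with other genes. The check genes with known C57BL/6J variants behaved alike in both other strains: Gabra2 was 1.60 higher in CAST/EiJ and 1.49 higher in NZO/HlLtJ than in C57BL/6J, and Nnt, whose sequences are shared in 48.5% with another annotated gene, 0.92 and 0.84 higher, with camera adjusted p = 1.6e-04 in NZO/HlLtJ (adjusted p = 0.0356 with an estimated correlation) and adjusted p = 0.00671 in CAST/EiJ (adjusted p = 0.225 with an estimated correlation).

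NZO/HlLtJ and CAST/EiJ differed in 10020 genes, 5469 higher and 4551 lower in NZO/HlLtJ. Interferon-stimulated genes were higher in NZO/HlLtJ in 19 of 20 cases and lower in 1 (median 1.18; camera adjusted p = 6e-07, adjusted p = 0.268 with an estimated correlation), with Ifi44 at 1.74 against 0.0627 CPM, Oasl2 at 2.90 (SE 0.13) and Irf7 at 2.50 (SE 0.12). Myelin genes were higher in 12 of 14 cases (median 0.40; camera adjusted p = 0.00146, adjusted p = 0.997 with an estimated correlation), with Mal at 0.70, Mobp at 0.65 and Aspa at 0.75. Fam213b was at 37.8 CPM in NZO/HlLtJ and 0.0214 CPM in CAST/EiJ. Its fitted difference of 11.56 rests on almost no counts in CAST/EiJ and is uncertain in size. Serpinb1a was 5.43 higher, while Thbs4 had a difference of -5.49, Tas1r1 of -4.79 and Tspan10 of -4.61. Kcnmb3, with 0.0331 CPM in NZO/HlLtJ, had a fitted difference of -7.75. Of the candidate genes from NZO crosses, Pctp was 0.88 higher and Abcg1 0.10 higher in NZO/HlLtJ.

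**Figure D4:**
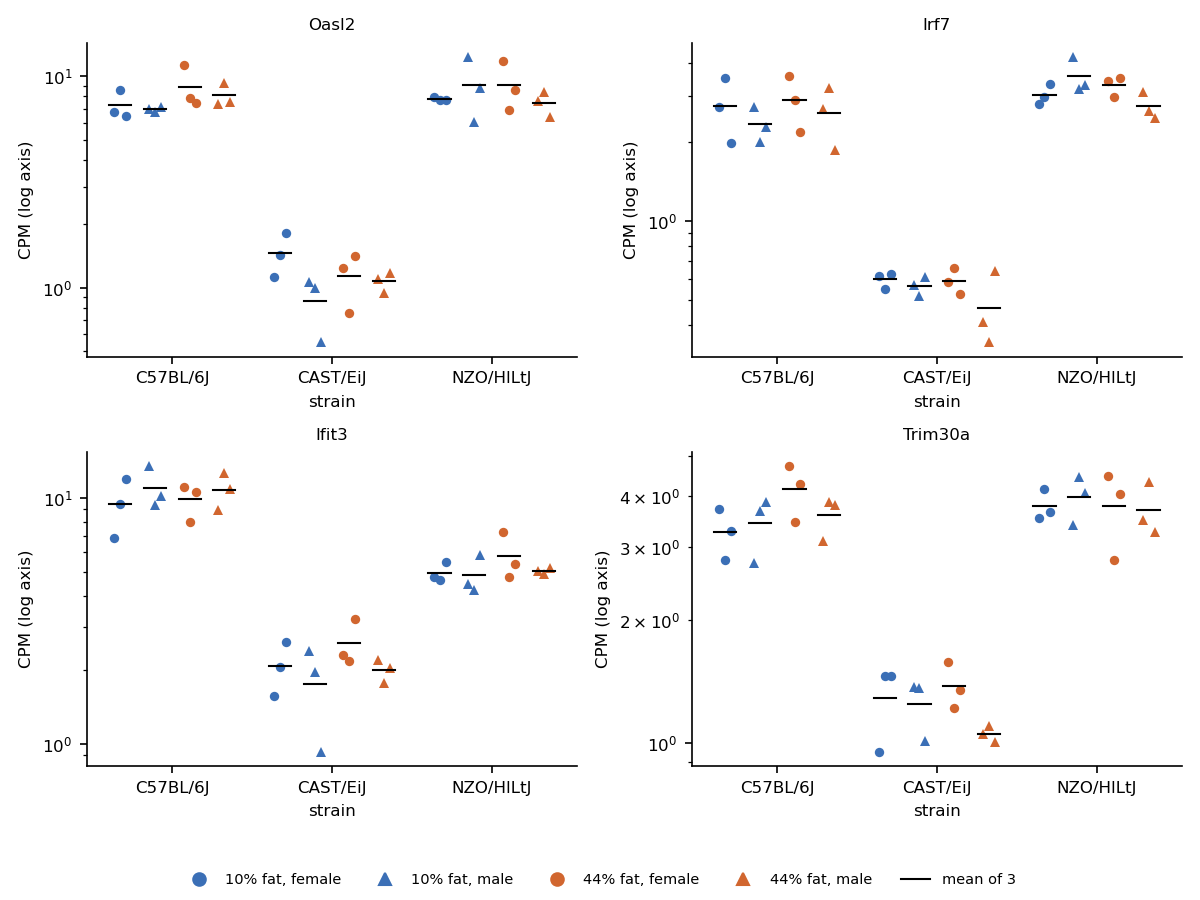
CPM on a log axis of the interferon-stimulated genes Oasl2, Irf7, Ifit3 and Trim30a in each of the 36 libraries, by strain, with the diet as colour, the sex as symbol and a line at the mean of 3 libraries. The CAST/EiJ libraries average 1.13 CPM of Oasl2, against 7.78 CPM in C57BL/6J and 8.34 CPM in NZO/HlLtJ.

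Several genes with extreme strain differences have a near-identical copy elsewhere, and their levels are uncertain. Rpl9-ps6 was at 150 CPM in C57BL/6J and 0.299 CPM in CAST/EiJ while Rpl9 was at 15.04 and 175.5 CPM, and the sum of both was 165.1 and 175.8 CPM. Eno1b, Amd2, AK157302 and Tuba1c were higher in CAST/EiJ than in both other strains. Tpm3-rs7 was at 0.136 CPM in C57BL/6J, 18.3 CPM in CAST/EiJ and 21.3 CPM in NZO/HlLtJ. Eno1b, Amd2, AK157302, Tuba1c and Tpm3-rs7 share between 53.7% and 85.7% of their 50-base sequences with other genes. Tmem254b had no counts in CAST/EiJ, so it was at least 3204-fold lower there than in C57BL/6J and at least 2791-fold lower than in NZO/HlLtJ, but its sequences all occur in Tmem254a, which was at 11.7 CPM in CAST/EiJ and 21.3 CPM in C57BL/6J. In NZO/HlLtJ, Hba-a1 was at 257.0 CPM against 1.85 CPM in C57BL/6J while its copy Hba-a2 was at 455.3 and 674.5 CPM, and Hist2h2aa2 shares all its sequences with Hist2h2aa1. The mitochondrial gene mt-Co2 was at 9.75 CPM in CAST/EiJ and 2554 CPM in C57BL/6J, and Gm28661, which holds 98.5% of its 50-base sequences, was at 4188 and 4058 CPM.

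Sex was compared within each strain, and the genes of the sex chromosomes led. In males of all 3 strains the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher, and Xist (ENSMUSG00000086503), which silences an X chromosome, was at 0.379 to 1.42 CPM in males and 692.5 to 817.5 CPM in females as strain means (SD up to 150.4, n = 6). Ddx3y had no counts in NZO/HlLtJ females and was at least 6256-fold higher in males. Genes that escape X inactivation were lower in males: all 6 in C57BL/6J and CAST/EiJ and 5 of 6 in NZO/HlLtJ, where Pbdc1 had a log2 value of -0.21, with Kdm6a between -0.64 and -0.50. Camera called both lists in every strain with the preset correlation and with an estimated correlation (largest adjusted p = 2.35e-06 with an estimated correlation). In all, edgeR called 15 genes in C57BL/6J (5 higher, 10 lower), 22 in CAST/EiJ (12 higher, 10 lower) and 15 in NZO/HlLtJ (8 higher, 7 lower). Autosomal genes among them were few: Apold1, an early gene of blood vessels, was lower in C57BL/6J males by a log2 change of -1.77 (SE 0.35, adjusted p = 0.0354 in edgeR's test; adjusted p = 0.0915 with the Hox score as a covariate). The clock gene Arntl (ENSMUSG00000055116) was 0.60 higher in CAST/EiJ males (SE 0.12, adjusted p = 0.0212 in edgeR's test), and was highest at 38.3 CPM in male control 3, 1 of the libraries almost lacking Hox reads. Its change was 0.55 without these libraries, a fit that keeps male control 2 as the only CAST/EiJ male control. The change was 0.41 with the Hox score as a covariate (adjusted p = 0.51 in edgeR's test). The lysosomal channel gene Tpcn2 was lower in NZO/HlLtJ males (-0.63, SE 0.12).

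In C57BL/6J, genes that respond to glucocorticoids were lower in males: 0 of 16 were called by edgeR over all genes, 12 were lower when adjusted over the list alone, and the median was -0.60 (camera adjusted p = 6.4e-17, adjusted p = 0.0259 with an estimated correlation). Its members Map3k6, Arrdc2, Ddit4 and Mt2 had log2 values of -1.003, -0.91, -0.78 and -0.51. Immediate early genes had a median of -0.64 and 7 of 14 members lower when adjusted over the list alone (camera adjusted p = 7.4e-14, adjusted p = 0.0744 with an estimated correlation), with Nr4a1 at 15.2 CPM in males and 30.9 CPM in females. With the Hox score as a covariate the medians of these lists were -0.48 and -0.65. Camera then called both with the preset correlation (adjusted p = 8.4e-11 and 2.4e-10). With an estimated correlation it called neither (adjusted p = 0.0995 and 0.188). DESeq2 called 32, 71 and 36 genes for sex in C57BL/6J, CAST/EiJ and NZO/HlLtJ, and the fits of only the strain's libraries 9 in C57BL/6J and NZO/HlLtJ. Without the 3 libraries almost lacking Hox reads 14 were called in CAST/EiJ and 258 in NZO/HlLtJ, where 3 tissue scores as covariates gave 14 and 10. Leaving out the 3 libraries keeps male control 2 as the only CAST/EiJ male control. The C57BL/6J count was 41 without female HFHS 3, and the CAST/EiJ count 666 without male control 2 and 13 without female control 3. Without male control 2, the CAST/EiJ male controls left almost lack Hox reads. The NZO/HlLtJ count was 35, 73 and 36 without male control 2, male control 3 and male HFHS 3.

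The effect of sex differed between strains for Nbr1 and Med14, the 2 genes called for the interaction of strain and sex (adjusted p = 0.0147 for both in edgeR's test). Nbr1 (ENSMUSG00000017119; chromosome 11, 101552149 to 101581951), a receptor of selective autophagy, was 0.58 higher in males of CAST/EiJ (SE 0.08), against -0.03 in C57BL/6J and -0.04 in NZO/HlLtJ. In CAST/EiJ its sex effect was 0.27 (SE 0.11) on the control diet and 0.89 (SE 0.11) on HFHS. The CAST/EiJ males differed among themselves, with 250.1 ± 67.65 CPM on control and 391.9 ± 67.1 CPM on HFHS (SD, n = 3). In the other groups the SD lay between 0.32 and 8.30 CPM. The SE comes from a spread shared over all groups and does not measure the spread of these males. Med14 (ENSMUSG00000064127; chromosome X, 12675369 to 12762073), a subunit of the Mediator complex, was lower in males of CAST/EiJ (-0.43, SE 0.05), against 0.07 in C57BL/6J and -0.04 in NZO/HlLtJ. DESeq2 called 228 genes, limma on the deposited log2 values 4, 2 surrogate variables 1, and the fits with Hox or 3 tissue scores 0. Without the 3 libraries almost lacking Hox reads, 1 was called. That fit keeps male control 2 as the only CAST/EiJ male control. Without male control 2, the CAST/EiJ male controls left almost lack Hox reads. Among fits without 1 library, the count was 407 without CAST/EiJ male control 2, and 140 and 74 without NZO/HlLtJ male control 3 and male HFHS 3. It was 4 without NZO/HlLtJ male control 1, male control 2 or C57BL/6J female control 3, 1 without CAST/EiJ male HFHS 1, female HFHS 3 or female control 2, and 0 without CAST/EiJ male HFHS 3 or female control 3.

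The effect of diet differed between the sexes for 5 genes in CAST/EiJ, all with a lower male than female effect. Gcnt1 (ENSMUSG00000038843; chromosome 19, 17326141 to 17372844), a glycosyltransferase gene, was at 21.7 ± 8.33 CPM in male controls and 3.73 ± 0.422 CPM in males on HFHS, against 5.03 ± 1.58 and 5.58 ± 3.31 CPM in females (SD, n = 3; interaction -2.69, SE 0.50, adjusted p = 0.0477 in edgeR's test). The ubiquitin ligase gene Rnf122 had an interaction of -1.88 (SE 0.36), D8Ertd82e of -1.11 (SE 0.20), Limd2 of -1.05 (SE 0.19) and the myosin gene Myo10 of -0.64 (SE 0.11). CAST/EiJ male controls include the 2 libraries with 1.15 and 1.93 CPM of Hox reads, and with the Hox score as a covariate edgeR called 0 genes. DESeq2 called 117 genes, the fits without a filter and on the deposited log2 values 3, the fit without the 3 libraries 2, and 2 surrogate variables, only CAST/EiJ libraries and 3 tissue scores 0. The fit without the 3 libraries keeps male control 2 as the only CAST/EiJ male control. Without male control 2, the CAST/EiJ male controls left almost lack Hox reads. Leaving out CAST/EiJ male control 2 gave 819 calls, female control 2 gave 9, female HFHS 3 gave 8, male control 3 gave 1, and any other CAST/EiJ library 0. It was 3 without any C57BL/6J library except female control 1 and female HFHS 3, and without NZO/HlLtJ female control 2, female control 3, female HFHS 3, male control 3 or male HFHS 2.

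In NZO/HlLtJ edgeR called 0 genes for the interaction of diet and sex (794 at an unadjusted p under 0.05, 15 by DESeq2), and in C57BL/6J 0 (680 at an unadjusted p under 0.05, 1 by DESeq2). Both numbers at an unadjusted p under 0.05 are fewer than chance alone would give. Feeding-related peptides in NZO/HlLtJ had a higher diet effect in males than in females: 0 of 21 were called over all genes, 11 were higher and 1 lower when adjusted over the list alone, and the median was 1.03 (camera adjusted p = 8.5e-17, adjusted p = 0.0216 with an estimated correlation). Penk had an interaction of 1.32 (SE 0.27), Gal of 2.90 (SE 0.66) and Npy of 2.36 (SE 0.55), none of them called. The male controls include male control 1, the library with reads of pituitary hormones. It held 3210 CPM of the list member Pomc, against at most 2.73 CPM in any other library, which lowers the male diet effect of Pomc. The Hox score was between 1.67 and 3.68 in the NZO/HlLtJ males on HFHS and between -3.09 and 0.16 in the male controls, and with that score as a covariate the list's median was 0.63 (camera adjusted p = 3.2e-06, adjusted p = 0.572 with an estimated correlation). The NZO/HlLtJ count was 10 without male control 3 and 1 without male control 1 or male control 2, and the C57BL/6J count 1 without male HFHS 3.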

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

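Tests of dissection, of blood and immediate early genes, and of diet, and the tests of the single copies Gm28661 and Gm13341, were chosen only after the results they concern had been seen; the tests of copies as a class, of the sum of mt-Co2 and its copy, and the splits of the libraries were written before, but the numbers of splits were settled after other draws had been looked at.

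In NZO/HlLtJ on HFHS, the 31 genes of the heat shock and stress response lists had a median change of -0.381 (quartiles -0.608 to -0.232), but only 3 of them were called lower, and camera with an estimated correlation called neither list (adjusted p = 0.11 and 0.122). Without the 3 libraries almost lacking Hox reads the median was -0.459 and camera with an estimated correlation called the heat shock list (adjusted p = 0.00699) but not the other (adjusted p = 0.061); the median was -0.376 (quartiles -0.542 to -0.254) with the Hox score in that model and -0.281 (quartiles -0.407 to -0.165) with the Hox, cerebellar and choroid plexus scores, which argues against dissection as the whole cause, but with these 3 scores the genes called went from 169 to 8 in that model and from 10 to 0 in all 36 libraries, where the median was -0.336 (quartiles -0.434 to -0.222). In the 33 libraries with the red blood cell and immediate early gene scores the median was -0.255 (quartiles -0.378 to -0.168), over 0.5 of its value without them, and fry called both lists lower, which argues against these states of the tissue as the whole cause, but the genes called went from 169 to 1 and those of the 31 called lower from 19 to 1; Hspa1b then had a log2 change of -2.88 (SE 0.463) instead of -3.90 (SE 0.523), and its adjusted p went from 7.9e-04 to 0.053 in edgeR's test, and whether the smaller effect or the adjustment over fewer passing genes ended its call was not tested. Diet remains open as a candidate explanation. In all 36 libraries the median was -0.372 in females and -0.5 in males. Of the 3 NZO/HlLtJ male controls, 1 holds reads of pituitary hormones and 1 almost lacks Hox reads. The latter, male control 3, had the lowest heat shock score of the NZO/HlLtJ controls (7.19). Leaving it out therefore widens the heat shock difference between the diets. Male controls 1 and 2 had 211.7 and 217 CPM of Hspa1a and Hspa1b summed, against 54.15 to 78.41 CPM in the other NZO/HlLtJ controls. The median without the library with pituitary reads was not computed. The labels give no collection days, so a shared handling of the HFHS libraries cannot be told apart from diet. Chance could not be excluded for the count of 10 genes, since 3 of 60 splits, the real one included, called as many or more. The highest other split of the same libraries called 84, which points to a structure of the samples.

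Diet in CAST/EiJ went together with the Hox content of the libraries. For the 50 called genes outside the red blood cell list, the Hox score in the model left a median of 0.519 of the diet effect (quartiles 0.387 to 0.706). This lies between the bounds of 0.5 and 0.75 set for the test. Leaving out the 3 libraries almost lacking Hox reads left 0.75 (quartiles 0.643 to 0.902), with male control 2 as the only CAST/EiJ male control. Dissection and diet therefore cannot be told apart for these genes. The 4 called red blood cell genes had diet effects within 0.247 log2 units of each other, but this test of blood in the tissue is void, because it used called genes alone and only Alas2 among them shares under 50% of its sequences with another gene; Hba-a1, not called, had a change of -1.93, and the source of these transcripts remains open. Chance could not be excluded for the count of 54, since 3 of 60 splits, the real one included, called as many or more. The highest other split called 1435. In that split the groups differed by 2.95 in the Hox score, against 3.53 in the real one, and a count so far above the real one points to a structure of the samples.

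Genes near absent in 1 strain and abundant in another often had a near-identical copy. Of 24 named genes with a strain difference beyond 5 log2 units, 11 (45.8%) share at least 50% of their 50-base sequences with another gene. Among all tested genes 4.43% do, a ratio of 10.4, so reads counted for a copy are a candidate explanation for these 11. For Tmem254b, 1 of them, the sum with its copy Tmem254a fell too, from 42.68 CPM in C57BL/6J to 11.7 CPM in CAST/EiJ. Reads counted for that copy do not account for its whole difference. Another 10 of the 24 share under 5%, and for them a copy was not supported as the explanation. For mt-Co2, 262-fold lower in CAST/EiJ, the sum with Gm28661 differed 1.58-fold, but this test is void, because Gm28661 is so abundant that the sum would differ 1.63-fold even if no read had moved. Gm28661 was higher in CAST/EiJ by 5.09% of the fall of mt-Co2, which argues against it as the place of the reads, and Gm13341 by 63.2%, which leaves it open. Gm13341 was at 1608 ± 484.2 CPM (SD, n = 12) in CAST/EiJ, 0.191 CPM in C57BL/6J and 0.214 CPM in NZO/HlLtJ. In the same order of strains mt-Co2 was at 9.75, 2554 and 2534 CPM. A difference between strains in mapping to the 1 named genome build was not tested. No biological explanation was tested beyond strain, which remains open.

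Across the other results, chance was excluded for the counts of the strain differences: 4792 genes for NZO/HlLtJ against C57BL/6J (highest other split 1), 10492 for CAST/EiJ against C57BL/6J (highest other 72) and 10020 for NZO/HlLtJ against CAST/EiJ (highest other 16). The other splits mix the strains of a pair, which turns strain differences into spread within groups and lowers their counts. They therefore speak for each count as a whole and say nothing about single genes. For sex in C57BL/6J (15 genes, highest other 2) and in CAST/EiJ (22, highest other 7) the other splits all called fewer. Every other split mixes the sexes and so loses the Y-linked genes and Xist. The splits therefore say nothing about the autosomal genes called for sex. Chance could not be excluded for the count of sex in NZO/HlLtJ (15, highest other 148, which points to a structure of the samples). Nor could it be for strain and sex (2, highest other 13) or for the interaction of diet and sex in CAST/EiJ (5, highest other 945, a structure of the samples). Counts of 0 leave nothing to exclude: diet in C57BL/6J (highest other 2), strain and diet (2), the diet differences of NZO/HlLtJ and C57BL/6J (5), CAST/EiJ and C57BL/6J (373) and NZO/HlLtJ and CAST/EiJ (1), and diet and sex in C57BL/6J (44) and NZO/HlLtJ (18), where 60 of 60 splits reach 0. Splits as large as the real one numbered 3 of 60 for diet in CAST/EiJ, for diet in NZO/HlLtJ and for strain and sex, 7 of 60 for sex in NZO/HlLtJ, 5 of 60 for diet and sex in CAST/EiJ, 1 of 60 for sex in C57BL/6J and in CAST/EiJ, and 1 of 30 for each pair of strains. A share of 3 of 60 lies at the limit of 0.05, and other draws of splits can fall on either side of it.

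Single libraries lay far from the other 5 of their strain and diet in 11 of 166 sets tested by Dixon's ratio, where about 1 in 20 does so by chance (8.3 expected). C57BL/6J male control 3 had a log2 CPM of 5.249 for Sgk1, against 7.526 to 8.313 (ratio 0.7432). CAST/EiJ male HFHS 3 had 2.704 for Pde11a, against 3.166 to 3.399 (ratio 0.6644), and CAST/EiJ female HFHS 3 had 7.666 for Cldn11, against 7.376 to 7.461 (ratio 0.7077). CAST/EiJ female HFHS 1 was high for 4 genes of the cerebellar neuron list: Etv1 (6.776; ratio 0.6899), Grm4 (6.795; ratio 0.65), Calb1 (7.05; ratio 0.7385) and Cbln1 (7.095; ratio 0.725). NZO/HlLtJ male control 1 was high for the endoplasmic reticulum and integrated stress response score (5.751, against 5.288 to 5.46; ratio 0.6293), Hmgn1 (6.03; ratio 0.7216) and Pdia3 (8.344, against 7.665 to 7.787; ratio 0.8201). NZO/HlLtJ male HFHS 1 had 5.76 for Pdia4, against 5.35 to 5.483 (ratio 0.6741).

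Interactions gave differences between groups. Nbr1 and Med14 had an adjusted p of 0.01473 in edgeR's test of strain and sex, with sex effects in CAST/EiJ of 0.5777 and -0.4281. In CAST/EiJ the diet effect of males minus that of females was -0.6376 for Myo10, -2.689 for Gcnt1, -1.882 for Rnf122, -1.047 for Limd2 and -1.112 for D8Ertd82e.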

How the results depend on the processing

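Settings without the 3 libraries almost lacking Hox reads, with the Hox score, and with 3 tissue scores, and the tests that use them, were chosen after seeing the data; the other alternatives were planned. Counts for the pairs of strains stayed within 1.5 times under the 9 alternatives other than leaving out 1 library: 4264 to 5141 for NZO/HlLtJ and C57BL/6J, 10218 to 10999 for CAST/EiJ and C57BL/6J, and 9883 to 10480 for NZO/HlLtJ and CAST/EiJ. Diet in C57BL/6J gave 0 in edgeR (525 at an unadjusted p under 0.05, fewer than chance alone would give) and 0 under its 10 alternatives, DESeq2 included. No paired analysis was possible because the labels carry no replicate numbers. Depth limits the genes with few counts, and 3 libraries per group limit the interactions, but neither number was varied. In the simulated counts 72 of 200 genes with a fold of 1.5 were recovered for diet and sex in CAST/EiJ, and 148 for diet in NZO/HlLtJ. At a fold of 4 these were 181 and 194.

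For other counts the cause was not tested. With DESeq2 the counts were 753 for diet in CAST/EiJ, 105 for diet in NZO/HlLtJ, 47 for strain and diet, 10, 7 and 60 for the diet differences of NZO/HlLtJ and C57BL/6J, CAST/EiJ and C57BL/6J, and NZO/HlLtJ and CAST/EiJ, 32, 71 and 36 for sex in C57BL/6J, CAST/EiJ and NZO/HlLtJ, 228 for strain and sex, and 1, 117 and 15 for diet and sex in C57BL/6J, CAST/EiJ and NZO/HlLtJ. Limma on the deposited log2 values gave 277 for diet in CAST/EiJ, 4 for strain and sex, and 3 and 1 for diet and sex in CAST/EiJ and NZO/HlLtJ. With 2 surrogate variables diet in CAST/EiJ gave 0, strain and sex 1, and diet and sex in CAST/EiJ 0. Only the strain's libraries gave 140 for diet in CAST/EiJ, 9 for sex in C57BL/6J and in NZO/HlLtJ, and 0 for diet and sex in CAST/EiJ. The additive model gave 5 for diet in CAST/EiJ, 23 for diet in NZO/HlLtJ and 1 for the diet difference of CAST/EiJ and C57BL/6J, and no filter gave 3 for diet and sex in CAST/EiJ. Without the 3 libraries the counts were 4 for diet in CAST/EiJ, 169 for diet in NZO/HlLtJ, 7 for strain and diet, 7 and 1 for the diet differences of NZO/HlLtJ and C57BL/6J and of CAST/EiJ and C57BL/6J, 14 and 258 for sex in CAST/EiJ and NZO/HlLtJ, 1 for strain and sex, and 2 and 17 for diet and sex in CAST/EiJ and NZO/HlLtJ. That fit keeps male control 2 as the only CAST/EiJ male control, so its counts that involve CAST/EiJ also rest on fewer libraries. The Hox score gave 0 for diet in CAST/EiJ, 5 for diet in NZO/HlLtJ, and 0 for strain and sex and for diet and sex in CAST/EiJ. With 3 tissue scores diet gave 0 in CAST/EiJ and NZO/HlLtJ, sex in CAST/EiJ 14, and strain and sex and diet and sex in CAST/EiJ 0. Of the 675 gene list tests, 148 passed with the preset correlation, 9 with an estimated correlation and 51 with fry.

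Leaving out 1 library in turn gave 0 to 3 genes for diet in C57BL/6J, 0 to 1928 in CAST/EiJ and 0 to 94 in NZO/HlLtJ, 0 to 42 for strain and diet, 0 to 6, 0 to 1 and 0 to 191 for the diet differences of NZO/HlLtJ and C57BL/6J, CAST/EiJ and C57BL/6J, and NZO/HlLtJ and CAST/EiJ, 4390 to 5129, 10275 to 10856 and 9709 to 10400 for the same pairs of strains, 12 to 41, 13 to 666 and 11 to 73 for sex in C57BL/6J, CAST/EiJ and NZO/HlLtJ, 0 to 407 for strain and sex, and 0 to 1, 0 to 819 and 0 to 10 for diet and sex in these strains. The diet difference of NZO/HlLtJ and C57BL/6J gave 6 without NZO/HlLtJ male control 3, 3 without C57BL/6J male control 2 and 1 without C57BL/6J female control 3; that of CAST/EiJ and C57BL/6J gave 1 without CAST/EiJ male control 3 or C57BL/6J female control 3; that of NZO/HlLtJ and CAST/EiJ gave 191 without CAST/EiJ male control 2, 124 without NZO/HlLtJ male control 3, and 1 without CAST/EiJ male control 3, C57BL/6J male control 2 or CAST/EiJ female HFHS 1. For the pairs of strains, 4390 and 5129 came without NZO/HlLtJ female HFHS 2 and male control 2, 10275 and 10856 without CAST/EiJ male HFHS 2 and NZO/HlLtJ male control 3, and 9709 and 10400 without NZO/HlLtJ female HFHS 3 and male control 3. The libraries behind the highest counts of the other ranges are named in the report. Where that library is CAST/EiJ male control 2, the CAST/EiJ male controls left almost lack Hox reads.

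Of 189 calls of named genes, 189 were kept with RLE size factors and with DESeq2, 182 without a filter, 185 on the deposited log2 values, 154 with 2 surrogate variables, 44 of 71 in the strain's libraries alone, 159 of 182 in the additive model, 157 without the 3 libraries, 151 with the Hox score, 145 with 3 tissue scores, and 143 in each of the 36 fits without 1 library; 0 reversed. Most of these calls are strain differences, and the others held less well. Of 20 for diet in CAST/EiJ, 0 were kept with 2 surrogate variables, without the 3 libraries, with the Hox score, with 3 tissue scores and in each fit without 1 library. A lost call need not be a lost change, and the fit without the 3 libraries keeps male control 2 as the only CAST/EiJ male control. Without the 3 libraries, the 4 red blood cell genes called for diet in CAST/EiJ kept a median of 0.992 of their effect. The other 50 called genes kept 0.75. Of 8 for diet in NZO/HlLtJ, 5 were kept with 2 surrogate variables, 8 without the 3 libraries, 4 with the Hox score, and 0 with 3 tissue scores and in each fit without 1 library. Of 16 for sex in CAST/EiJ, 11 were kept with the Hox score and in each fit without 1 library, against 11 and 10 of 12 in C57BL/6J and 10 and 8 of 10 in NZO/HlLtJ. Of 2 for strain and sex and 5 for diet and sex in CAST/EiJ, 0 were kept with the Hox score or in each fit without 1 library. Named genes that were not called reversed in some settings, and the cause was not tested. For diet in CAST/EiJ the Hox score gave Serpina3n -0.03016, Grm4 0.1396, Calb1 0.1959, Cbln1 0.1618 and Sall1 -0.0537, 3 tissue scores gave Grm4 0.01004, Calb1 0.0907, Cbln1 0.02134 and Sall1 -0.05357, and 2 surrogate variables gave Calb1 0.04212. Tbc1d1 was 0.004168 for NZO/HlLtJ and C57BL/6J with 3 tissue scores and 0.01211 for NZO/HlLtJ and CAST/EiJ with 2 surrogate variables. For CAST/EiJ and C57BL/6J it was 0.005241 with RLE, 0.004748 with DESeq2, 0.001947 without a filter, 0.005854 on the deposited log2 values, 0.04898 without the 3 libraries, 0.05044 with 3 tissue scores, and -0.01397 to 0.03493 without 1 library. Without 1 library, Lepr for NZO/HlLtJ and C57BL/6J ran from -0.03615 (without NZO/HlLtJ male HFHS 2) to 0.09904 and Abcg1 for CAST/EiJ and C57BL/6J from -0.03804 to 0.002305 (without CAST/EiJ male control 2).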

Other observations

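The test of pituitary tissue described here used markers whose values had not been looked at, while its idea came from values already seen. NZO/HlLtJ male control 1 held 11710 CPM of Gh, 2535 CPM of Prl and 3210 CPM of Pomc, which were 1.82% of its counts, against at most 7.31, 14.98 and 2.73 CPM in the other 35 libraries. A candidate explanation is pituitary tissue in that library. Of 8 other pituitary markers in the table, 8 (100%) had their highest CPM of the 36 libraries there, among them Gnrhr at 11.9 CPM (highest other 0.104), where chance gives 2.78% for each. The same library had the far values of the stress response score, Hmgn1 and Pdia3 among the NZO/HlLtJ controls, and without it edgeR called 2 genes for diet in NZO/HlLtJ.

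Y-linked genes summed to 3.58 CPM in C57BL/6J female control 1.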
